A study of Gallus gallus with 2 samples.

How the data were processed

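Small RNA of 2 whole-embryo libraries of the Lingnan Yellow breed was analysed, 1 library from stage X and 1 from stage HH10. Per the labels, total RNA was extracted with Trizol, RNA of 18 to 33 nt was cut from a gel, adaptors were ligated to both ends, and the products were sequenced on the Illumina 1G Genome Analyzer. The deposited files hold raw counts, 1 line for each distinct sequence with its length and its number of reads per the file headers, and adaptors are already removed. The trimming tool, quality filter, aligner and genome build were not given in the sources used here. The recorded length equalled the number of bases on every line. Lengths ran from 3 to 30 nt, so the top of the gel window, above 30 nt, was not analysed here, and reads shorter than 18 nt (24.7% of the reads at stage X and 34.9% at stage HH10) were left out of the length profile.

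Depth was 10825756 reads at stage X and 10053212 at stage HH10. The highest level that a count of 0 was taken to allow, 3 counts of the total, was 0.277 reads per 1000000 at stage X and 0.298 at stage HH10. With 1 library per stage no test between stages was made and no p-value is given. Shares have exact Clopper-Pearson 95% intervals and ratios have the exact interval of a ratio of 2 Poisson counts, both for counting error only. A seed or group was called higher or lower where the ratio was at least 2-fold and its interval left out 1, with an offset of 0.5 reads in the log2 ratio.

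No genome was used here. The planned split of reads into RNA classes, the genomic windows of piRNA-like reads, the removal of structural RNA, the match of tags with up to 1 mismatch and the limit to reads with 1 place in the genome were therefore not run, and tags carry no gene names or positions. The piRNA range of 24 to 31 nt became 24 to 30 nt, and 26 to 32 nt became 26 to 30 nt. Levels of miRNAs were taken from 20 to 24 nt tags whose bases 2 to 8 equal 1 of 52 seeds of miRNA lists fixed before the data were examined. The plan included both arms of each miRNA precursor, but each miRNA was counted by 1 seed. Reads from the other arm were therefore left out unless they carried a listed seed. The main scaling was the sum of these seed reads (ratio of stage HH10 over stage X 3.01), in place of all miRNA reads. The alternatives were the reads of the library (0.929), TMM (2.43) and DESeq2 size factors (2.09), the last pair computed over the seeds.

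A seed alone does not identify a miRNA. Each seed was therefore compared with the 95th percentile of reads over all 16223 seeds of 7 bases (605.8 reads at stage X and 325.0 at stage HH10), which 35 of the 52 passed in at least 1 library. Each seed was also checked for how many of its reads go on as the textbook mature miRNA over bases 2 to 11. This check was added after the data were seen, and 40 seeds had more than 50% of their reads so continued, with 96.1% of all seed reads at stage X and 98.5% at stage HH10. For each fixed list with at least 3 seeds of at least 10 reads, the median log2 ratio was ranked among 10000 random lists of the same size, drawn for each seed from the 100 seeds nearest in mean level.

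The 5′ overlap of opposite-strand tags was counted without a genome. For each overlap of 9 to 16 nt, all sequence windows of the overlap plus 5 bases on each side were collected from tags of at least 18 nt, on both strands. The share was the windows with a tag starting 5 bases in that also held a tag of the other strand starting 5 bases from the other end. Each distinct window counts once, whatever its reads. The window reaches 5 bases beyond the 5′ end of each paired tag, so a pair counts only where a further tag covers the window. A pair is seen in a window and again in the reverse complement of that window, so the intervals of these shares are too narrow. The other overlaps planned, under 9 nt and above 16 nt, were not run because such windows are too common by chance or longer than most tags. Groups of tags share their first 18 nt.

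Named seeds were, by the rule fixed beforehand, the 10 most abundant in each library, up to 12 with the largest ratio in each direction among those with at least 100 reads in 1 library and a call, and list members with at least 100 reads. Of the seeds with fewer reads, miR-194 and miR-199 are named because they complete the count of seeds lower under all scalings, and miR-133, miR-217 and miR-219 because their direction turned under an alternative. Named tags were the 5 most abundant of each library in the 20 to 23 nt and the 24 to 30 nt range. Calls were tested on simulated counts with the real means and depths. Of 200 groups changed 4-fold (log2 of 2), 84.0% were called among 27015 groups of 20 to 24 nt and 82.5% among 19467 groups of 24 to 30 nt, with 1.91% and 1.84% of unchanged groups called. Among the 52 seeds all 10 changed seeds were called and 0 others. These counts were drawn with Poisson error alone and scaled to library reads. The rates therefore cover counting error and not variation between libraries. In tags from a random sequence the 10 nt share was 0.933 times its neighbours with no planted pairs and 2.10 times with 1500 planted pairs.

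The alternatives tried were distinct tags in place of reads, size ranges of 23 to 29 and 26 to 30 nt, tags read at least 2 times, the 4 scalings, no minimum or at least 100 reads in 1 library, and an offset of 5 reads. Added after the data were seen were all reads as the denominator, a thinned stage X library, the removal of the 1000 most abundant groups of tags with the same first 14 nt, seeds above the 95th percentile and reads with the textbook continuation. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and matplotlib 3.10.9 for the plots.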

Results

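Small RNA was sequenced from whole chicken embryos at 2 points of early development, with 1 library for each. Embryos at stage X, before gastrulation, came from freshly laid eggs that had not been incubated. Embryos at stage HH10 (Hamburger and Hamilton stage 10), after gastrulation, came from eggs incubated for about 30 h at 37.8 °C. The stage X library held 10825756 reads of 1058704 distinct sequences, called tags here, and the stage HH10 library held 10053212 reads of 714266 tags. Reads inside the 18 to 30 nt range that the gel window and the files share numbered 8151692 at stage X and 6545706 at stage HH10. There were no replicate libraries, so no difference had a replicate check, and higher and lower compare the 2 libraries rather than the stages. Intervals are exact 95% intervals for counting error only, since PCR reads without molecular identifiers are not independent molecules. No genome was used here, so tags are reported by sequence and count, and only miRNA seed families fixed before the data were examined carry names.

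The first question was which kinds of small RNA each stage held, read from their length. Stage X held a broad population of longer small RNAs that was much reduced in the stage HH10 library. Reads of 24 to 30 nt, the range of Piwi-interacting RNAs (piRNAs, which silence transposons in the germ line), made up 42.0% of the 18 to 30 nt reads at stage X (interval 41.97 to 42.04) and 19.95% at stage HH10 (19.92 to 19.98). The contrast was larger among 26 to 30 nt reads, with 24.8% at stage X against 5.86% at stage HH10. Reads of 20 to 23 nt, the usual length of miRNAs, made up 43.9% at stage X (43.82 to 43.89) and 63.4% at stage HH10 (63.34 to 63.41). Length alone does not make them miRNAs. The fixed miRNA seeds held 9.87% of the 20 to 24 nt reads at stage X and 25.9% at stage HH10. Reads that end in 3 or more T were also more frequent at stage HH10, with 20.3% of the 18 to 30 nt reads against 4.43% at stage X. They include the most abundant 20 to 23 nt tag of stage HH10. The most frequent length was 22 nt in both libraries, with 14.01% of the reads at stage X and 23.6% at stage HH10. A small secondary maximum of reads lay at 26 nt at stage X (9.15%) and was not seen at stage HH10, where 26 nt held 2.57%. Over distinct tags of stage X it was absent, with 8.27% at 25 nt and 7.91% at 26 nt. A single 26 nt tag held 84712 of the 745912 stage X reads of that length, against 715113 reads at 25 nt. At 24 nt the share was 8.46% at stage X and 11.3% at stage HH10, and 24 nt tags with the miR-30 seed led that length class at stage HH10.

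**Figure D1:**
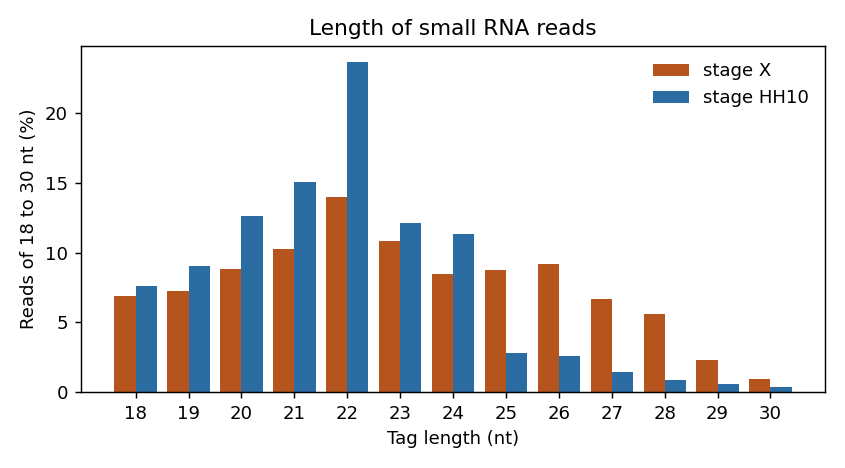
Share of the 18 to 30 nt reads (vertical axis, percent) at each tag length (horizontal axis, nt) in the stage X and stage HH10 libraries, 1 library each. At 22 nt the bars reach 14.01% at stage X and 23.6% at stage HH10, while at 26 nt they reach 9.15% and 2.57%.

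The stage X library also held more kinds of sequence. After random thinning of the stage X library to the depth of the stage HH10 library, it still held 1025387 distinct tags against 714266. The 10 most abundant tags took 7.48% of the stage X reads (interval 7.47 to 7.50) and 22.5% of the stage HH10 reads (22.45 to 22.50). Tags read once made up 42.4% of the tags at stage X and 52.7% at stage HH10, which amounted to 4.15% and 3.74% of the reads.

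The 5 most abundant tags of each library in each size range were then compared. Among 24 to 30 nt tags of stage X the most abundant was TCGAGATCACGAACTCAACCAGTGCATG, a 28 nt tag with 11091 reads per 1000000 reads of the library (RPM) at stage X and 386.5 at stage HH10, 28.7-fold higher at stage X (interval 27.8 to 29.6). The next at stage X, GCATTGGTGGTTCAGTGGTAGAATTC, stood at 7825 and 3406 RPM, 2.30-fold higher at stage X. At stage X the fourth, TCCGGAGAGGGAGCCTGAGAAACGG, was 10.7-fold higher at stage X (10.33 to 11.02), and the fifth, GAGGTGTAGAATAAGTGGGAGGCCC, was 2.34-fold higher there. Known structural RNA was not removed, so the length of these tags does not make them piRNAs. At stage HH10 the leading 24 to 30 nt tag was TGTAAACATCCCCGACTGGAAGCT, with 25877 RPM against 4693 at stage X, 5.51-fold higher at stage HH10 (5.46 to 5.57). Its near relatives TGTAAACATCCTCGACTGGAAGCT and TGTAAACATCCTTGACTGGAAGCT, which share the miR-30 seed, were 28.8-fold (28.1 to 29.6) and 5.94-fold higher at stage HH10. AGCTACATCTGGCTACTGGGTCTC, with the seed of miR-221 and miR-222, was 2.67-fold higher at stage HH10.

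Among 20 to 23 nt tags, GTACAGTACTGTGATAACTGAA was the most abundant at stage X, with 12711 RPM, and stood at 24509 at stage HH10, 1.93-fold higher (1.92 to 1.94). GGTGGACAGCGGTCACTTTT led at stage HH10 with 30639 RPM against 4047 at stage X, 7.57-fold higher (7.49 to 7.65). CAGGCTGGTTAGATGGTTGTCT was 11.3-fold higher at stage HH10 (11.1 to 11.5), while CAGGCTGGTTAGATGGTTGTCC was 1.86-fold higher. TCACAGTGAACCGGTCTCTTT, with the miR-128 seed, was 15.3-fold higher at stage HH10 (15.0 to 15.6), and ACAGGGCGCGGCGCCCACTTT was 7.76-fold higher. TACCACAGGGTAGAACCACGGAC was 2.91-fold higher at stage HH10, and ACTTAAATGTGGATGTGCTTGCT differed least of these, at 1.14-fold higher at stage HH10 (1.12 to 1.15).

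The next comparison asked whether the 24 to 30 nt reads carried the marks of piRNAs, which usually start with U (T in the tags) and, when made by the ping-pong cycle, pair with opposite-strand piRNAs whose 5′ ends overlap by 10 nt and carry A as base 10. Both libraries showed the 10 nt overlap, and its share of windows was several times higher at stage X, as were those of its 9 and 11 nt neighbours. At stage X 3.07% of the sequence windows that held the start of a 24 to 30 nt tag also held an opposite tag overlapping by 10 nt (2926 of 95203 windows, interval 2.96 to 3.19). The shares at 9 nt and 11 nt were 1.94% and 1.44%, and the mean over the 7 other overlaps of 9 to 16 nt was 1.13% ± 0.448 (SD over overlaps). At stage HH10 the share at 10 nt was 0.787% (310 of 39369 windows, 0.702 to 0.880), against 0.420% ± 0.0373 over the 7 other overlaps. A pair counts in the windows of both strands, so the intervals of these shares are too narrow. It also counts only where a further tag covers the window, so the shares can depend on how densely the tags of a library overlap. Each overlap rests on another set of windows, with 95203 at 10 nt and 27551 at 16 nt at stage X. Against the mean of its 9 and 11 nt neighbours the 10 nt share was 1.82 times as high at stage X and 1.85 times at stage HH10. The 20 to 23 nt tags also peaked at 10 nt at stage X, with 1.38% (1.31 to 1.45, 1.85 times its neighbours), but at stage HH10 their 0.924% was 1.11 times its neighbours, and the interval of 0.846 to 1.01 took in the share at 9 nt, 0.899%.

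**Figure D2:**
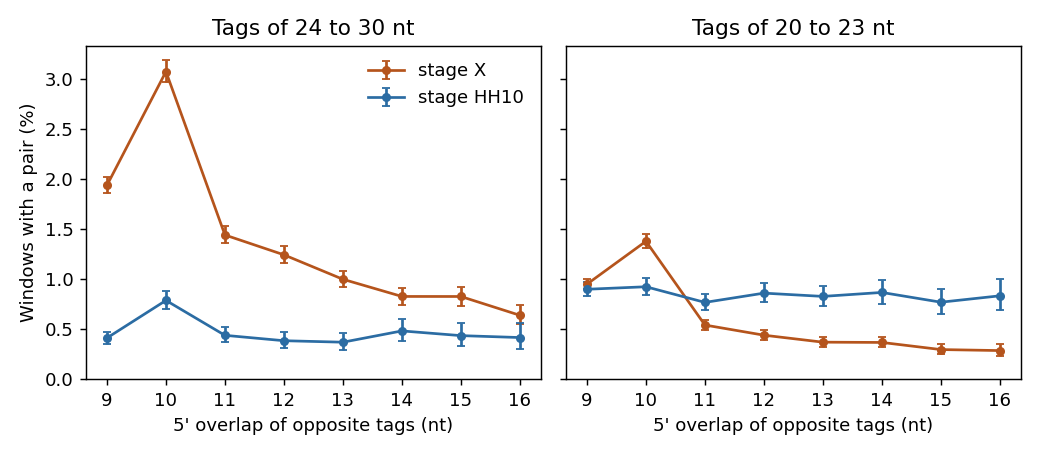
Share of sequence windows with a tag start that also hold an opposite-strand tag (vertical axis, percent), by the overlap of the 5′ ends (horizontal axis, nt), for 24 to 30 nt tags (left) and 20 to 23 nt tags (right) of the stage X and stage HH10 libraries, 1 library each. Points are shares and bars are exact 95% counting intervals, and the 24 to 30 nt share peaks at 10 nt with 3.07% at stage X and 0.787% at stage HH10.

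In both libraries the tags that paired at 10 nt started with T more often than tags paired at 9 nt. At stage X 18704 such tags held 18.6% of the 24 to 30 nt reads. T was the first base of 63.3% of them (interval 62.6 to 64.0), against 54.3% for tags paired at 9 nt (53.3 to 55.2). At stage HH10 819 tags paired at 10 nt, with 0.422% of the 24 to 30 nt reads. T was the first base of 59.5% of them (56.0 to 62.8), against 31.7% for tags paired at 9 nt (27.3 to 36.3). Tags that differ only at the 3′ end share their first base but were counted separately, so these intervals are too narrow in both libraries. In such a pair base 10 of a tag lies opposite the first base of its partner, so A as base 10 is no separate mark there. Tags paired in either library reached 58926 RPM at stage X and 2615 at stage HH10, 22.5-fold higher at stage X (22.3 to 22.8). The choice of tags mostly came from the stage X library, but the pooled reads of the 819 tags paired at stage HH10 were also 14.3-fold higher at stage X (13.96 to 14.7), with 7861 against 548.1 RPM. Abundant tags carried that sum. Tag by tag, scaled to library reads, 308 of the 819 were lower at stage HH10, 4 were higher and 507 were neither, among them most of the 327 tags with no stage X reads, which had at most 7 reads each at stage HH10.

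Over all 24 to 30 nt reads, A was base 10 of 33.4% at stage X (33.39 to 33.49) and 15.94% at stage HH10 (208123 of 1305892 reads). The contrast was smaller over distinct tags, at 32.8% and 25.9%. For 20 to 23 nt reads the corresponding shares were 23.9% and 20.2%. T as first base went the other way, with 40.2% at stage X (40.20 to 40.30) and 52.3% at stage HH10 (52.26 to 52.43), and this direction turned when abundant tags were given less weight. It was 32.6% at stage X against 25.5% at stage HH10 over distinct tags, and 43.1% against 23.3% over reads of 26 to 30 nt, which leave out the 24 nt tags with the miR-30 seed. Known structural RNA could not be removed from these reads.

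Tags were then pooled by their first 18 nt, so that variants with different 3′ ends counted together. Of 2828 such groups of 24 to 30 nt tags with at least 100 reads in 1 library, 2315 (81.9%) were lower at stage HH10 by at least 2-fold with a counting interval that left out 1, and 172 were higher, scaled to the reads of the library. Their median log2 ratio of stage HH10 over stage X was -3.56. Of the 335 groups that held a tag paired at 10 nt in either library, 333 were lower and the median was -4.74, but pairing was mostly seen at stage X and so selects tags of that library. Of the 2493 groups with no paired tag 1982 were lower, with a median of -3.24. With no minimum of reads, 343 groups held a tag paired at stage HH10, of which 155 were lower, 2 higher and 186 neither, with a median of -1.48 and 108 without stage X reads. In the 20 to 24 nt range 1837 of 3482 groups (52.8%) were lower at stage HH10 and 797 (22.9%) were higher, with a median of -1.18. Scaled to miRNA seed reads instead, 2616 groups of 24 to 30 nt were lower and 39 higher, and 2545 groups of 20 to 24 nt were lower and 197 higher.

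The last comparison addressed the miRNAs of each stage, counted as 20 to 24 nt reads that carried 1 of 52 miRNA seeds (bases 2 to 8) fixed before the data were examined. Reads with the seeds of miR-124, miR-128, miR-375, miR-30 and several epithelial and sensory miRNAs were higher at stage HH10. Those of let-7, miR-302, miR-122, miR-451 and the seed shared by miR-192 and miR-215 took a smaller part of the seed reads there. Seed reads made up 3.89% of the stage X library (interval 3.88 to 3.90) and 12.59% of the stage HH10 library (12.57 to 12.61). Scaled to these seed reads, 9 seeds were at least 2-fold higher at stage HH10, 20 were lower and 23 were neither. Of the 20 lower seeds 10 had most of their reads go on as the textbook mature miRNA, and over such reads alone 17 seeds were higher and 9 lower. Scaled to all reads of the library, which moved every log2 ratio up by 1.70, 29 were higher and 9 lower. With TMM scaling 12 were higher and 17 lower, and with DESeq2 size factors 15 were higher and 16 lower. Log2 ratios of stage HH10 over stage X below are scaled to seed reads. The sign turned when scaled to library reads for 16 of the 52 seeds, 4 of them called.

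The 9 seeds higher at stage HH10 scaled to seed reads were higher under all 4 scalings. That is no added support, because each alternative scaling moves all log2 ratios up by a constant. Reads with the miR-124 seed, a miRNA of neurons, had the highest ratio when all reads of a seed were counted. Its log2 was 2.10 (2.01 to 2.19), from 1036 to 13324 reads. miR-128, also neural, stood at 1.93 (1.91 to 1.96) and was the second most abundant seed at stage HH10 with 142036 reads. miR-375, known from pancreatic islets, stood at 2.02 (1.83 to 2.22). The sensory organ miRNAs miR-182 and miR-183 stood at 1.84 (1.54 to 2.17) and 1.05 (0.82 to 1.28). At stage X 48.4% of the reads with the miR-182 seed go on as miR-182. Over such reads alone its log2 was 2.80, above the 2.12 of miR-124 counted in that way. Of the epithelial miRNAs, the seed of miR-200 and miR-429 stood at 1.18 (1.06 to 1.30), miR-205 at 1.08 (0.54 to 1.70) and miR-203 at 1.01 (0.95 to 1.06). miR-30 was the most abundant seed at stage HH10, with 498815 reads against 70354 at stage X and a log2 of 1.24 (1.23 to 1.25).

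The 9 seeds called lower at stage HH10 scaled to library reads were lower under all 4 scalings. This follows because the other scalings give lower ratios, and it is no added support. Of these seeds 4 were carried mainly by tags that go on as the textbook mature miRNA. Reads with the seed of miR-192 and miR-215, known from gut and kidney, were furthest below stage X, with 4490 reads at stage X, 239 at stage HH10 and a log2 of -5.82 (-6.01 to -5.63). miR-451, a miRNA of red blood cells, stood at -4.62 (-4.82 to -4.42). miR-122, known from liver, was the fifth most abundant seed at stage X with 29384 reads and stood at -3.29 (-3.32 to -3.25). miR-194 stood at -3.47 (-4.37 to -2.71) on 64 and 17 reads. The other 5 seeds (miR-199, miR-140, miR-142, miR-153 and miR-208) were carried mostly by tags that do not continue as those miRNAs, so their ratios of -4.07, -3.36, -3.01, -2.93 and -2.78 do not describe the named miRNAs. The same held for miR-9, at -1.90.

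let-7, a family that accompanies differentiation, was the most abundant seed at stage X with 71530 reads, against 37442 at stage HH10. Its log2 was -2.52 (-2.54 to -2.50), and -0.83 scaled to library reads, where it did not reach 2-fold. miR-125, which often acts with let-7, stood at -2.65 (-2.78 to -2.53) and at -0.96 scaled to library reads. miR-302, the early embryo and stem cell miRNA, was the third most abundant seed at stage X with 49907 reads. It stood at -2.09 (-2.11 to -2.07), and at -0.39 scaled to library reads, also short of 2-fold. miR-96 stood at -1.40 (-1.80 to -1.001), and turned to 0.29 scaled to library reads and to 1.45 when only reads that go on as the mature miRNA were counted.

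The remaining abundant seeds differed by less than 2-fold scaled to seed reads. These were the seed of miR-1 and miR-206 of muscle (33722 reads at stage X and 85802 at stage HH10, log2 -0.24), the seed shared by miR-367, miR-92 and miR-363 (27886 and 56221, -0.58), the seed of miR-103 and miR-107 (20299 and 84020, 0.46), the seed of miR-130, miR-301 and miR-454 (16643 and 93214, 0.90), the seed of miR-221 and miR-222 (15962 and 55293, 0.20) and miR-21 (13796 and 28230, -0.56). Scaled to library reads each of these was more than 2-fold higher at stage HH10, with log2 ratios of 1.45, 1.12, 2.16, 2.59, 1.90 and 1.14.

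**Figure D3:**
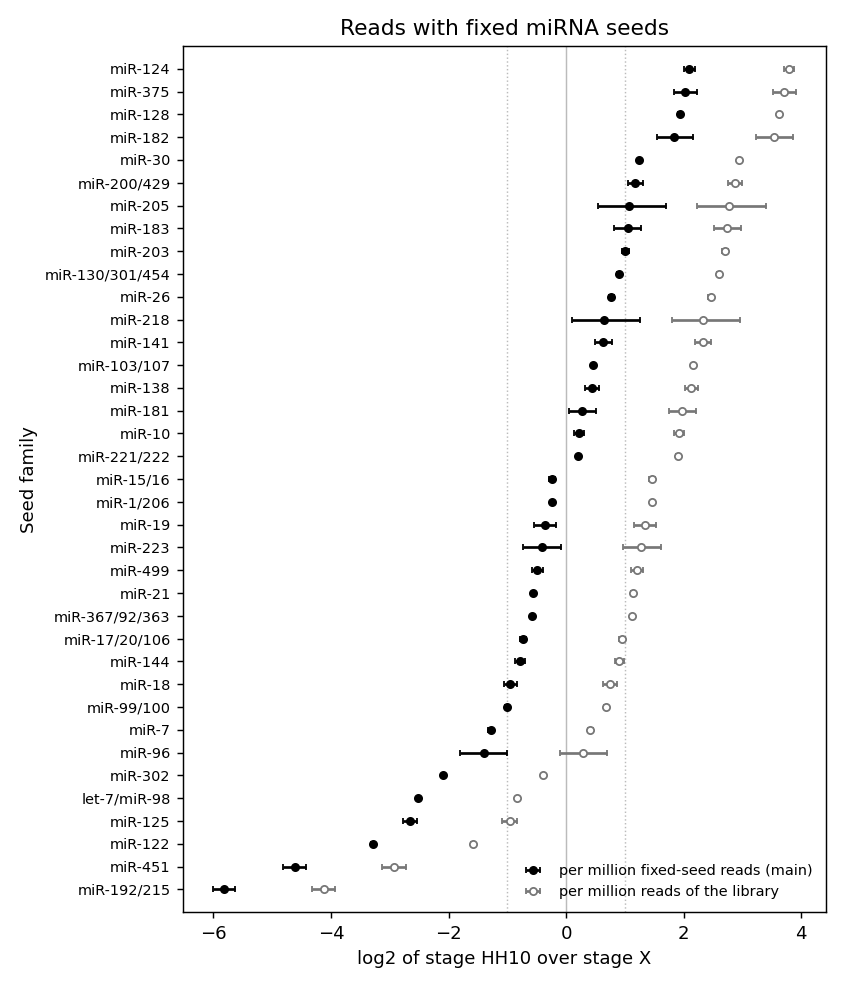
Log2 ratio of stage HH10 over stage X (horizontal axis) for the 37 seed families (vertical axis) with at least 100 reads in 1 library that were carried mainly by textbook mature tags, 1 library per stage. Filled points are scaled to fixed-seed reads and open points are scaled to library reads, with exact 95% counting intervals, and dotted lines mark 2-fold. miR-124 lies highest at 2.10 and 3.79, and the seed of miR-192 and miR-215 lies lowest at -5.82 and -4.12.

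Grouped by the lists fixed beforehand, the epithelial list (miR-141, miR-200 with miR-429, miR-203 and miR-205) had 4 members with at least 100 reads, of which 3 were higher at stage HH10 and miR-141 was not (log2 0.63), while scaled to library reads all 4 were higher (miR-141 at 2.33). Its median of 1.04 lay at the 99.97 percentile of 10000 random lists of other seeds matched on mean level, a description of these libraries and not a test. The seeds drawn on had a median log2 of -2.73, against -0.52 for the fixed miRNA seeds. A list of miRNA seeds can therefore rank high whatever its tissue, as the vessel and blood list did with a median of -0.79 (99.48 percentile). The sensory list had a median of 1.05 (99.99 percentile) with miR-182 and miR-183 higher and miR-96 lower, the latter a direction that turned when scaled to library reads. The neural list had a median of 0.51 (above all 10000 random lists). Of its 6 members with at least 100 reads, 4 were carried mainly by textbook tags. miR-124 and miR-128 were higher, while miR-138 (0.44) and miR-218 (0.64) were not called. Scaled to library reads these were higher as well, at 2.13 and 2.34, and over reads that go on as the mature miRNA miR-218 was called higher at 1.06. The widely expressed list had a median of 0.27 (99.26 percentile) with 1 of 7 members, miR-30, higher, and all 7 higher scaled to library reads.

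The miR-17-92 list, with 4 members and none called, had a median of -0.66 (93.84 percentile), which turned to 1.04 scaled to library reads, where 2 of the 4 were higher (the seed of miR-367, miR-92 and miR-363 at 1.12 and miR-19 at 1.34). The vessel and blood list (-0.79, 99.48 percentile) held miR-451 as its lower member, with miR-144 at -0.79 and miR-223 at -0.42, which turned to 0.91 and 1.28 scaled to library reads, as the median did to 0.91. At stage X 25.9% of the reads with the miR-144 seed go on as miR-144, and over such reads alone its log2 was 1.05, a call of higher at stage HH10. The muscle and heart list (-1.33, 89.81 percentile) had miR-1 with miR-206 and miR-499 (-0.49) as members carried mainly by textbook tags over both libraries, neither called. Its median was lowered by the miR-133 and miR-208 seeds, whose reads mostly do not go on as those miRNAs, and it turned to 0.47 over reads that do and to 0.36 scaled to library reads. At stage X 13.3% of the reads with the miR-499 seed go on as miR-499, and over such reads alone its log2 was 2.29 (178 reads at stage X and 2687 at stage HH10), called higher, while over all its seed reads it turned to 1.21 scaled to library reads. The endoderm organ list had a median of -2.65 (45.97 percentile), with miR-375 higher and miR-122, miR-192 with miR-215, and miR-7 lower, although miR-7 turned from -1.28 to 0.41 scaled to library reads. The mesenchyme list (-3.36, 22.74 percentile) had no member with at least 100 reads that was carried mainly by textbook tags. The other arm of these miRNAs, miR-140 included, was not counted, so the list value covers the listed seeds only. The lists with fewer than 3 seeds give values only. Of the miR-125 seed and the seed shared by miR-99 and miR-100 both were lower, but the latter turned from -1.01 to 0.68 scaled to library reads. In the Hox list miR-10 stood at 0.23, and at 1.92 scaled to library reads, where it was called higher. The miR-196 seed stood at -1.20 and turned to 0.49 scaled to library reads, but 11.5% of its stage X reads go on as miR-196, and over such reads alone it was called higher, at 1.32. The random lists had median values between -2.83 and -2.31, since most other seeds were lower at stage HH10 on this scale.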

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

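The tests on dilution, on the most abundant groups and on adaptor bases were chosen after the results they bear on had been seen, as was the breakdown of the T runs by stem.

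The higher share of 10 nt overlaps at stage X, where the 9 and 11 nt overlaps were higher too, was set against 3 technical explanations. Thinning the stage X library to the 24 to 30 nt reads of stage HH10 left its share at 3.24%, against 0.787% at stage HH10. That argues against the number of 24 to 30 nt reads as the cause. The thinned library still held 193403 tags of this range against 126848 at stage HH10, so the number of distinct tags was not matched. Nor was the cover of windows by further tags, on which the share also depends. Dilution by other fragments at stage HH10 would lower paired and miRNA seed reads alike. The pooled reads of the 819 tags paired at stage HH10 were, per seed read, 0.0215 times as frequent there as at stage X (interval 0.0209 to 0.0221). Without the 100 tags most abundant at stage X the value was 0.0557 (0.0528 to 0.0587). Tag by tag 384 were lower, 0 higher and 435 neither, with 327 not read at stage X. The pooled paired reads thus did not move alike with seed reads. That compares read levels and not the share of windows, and seed reads themselves rose from 3.89% to 12.59% of the library. Dilution of the share therefore cannot be decided here. Without the 1000 most abundant 5′ groups of each library the share was 2.73% at stage X (2.63 to 2.84) and 0.862% at stage HH10. Each distinct window counts once whatever its reads, so abundant tags had little weight in the share from the start. This test therefore cannot decide on a few abundant tags. A hypothesis that stays open is that piRNAs deposited by the mother or made in the germ cells are a large part of the small RNA before gastrulation and may be diluted later by growing somatic tissue with miRNAs of its own, which these 2 whole-embryo libraries did not test.

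Reads that end in a run of T were outside the main comparisons and made up 9.04% of the 12 to 30 nt reads at stage X and 31.8% at stage HH10 (3 or more T), and most came from 20 leading stems that took 85.2% of those reads at stage HH10. The adaptor starts with a single T, and with 1 T taken off 73.2% of the reads with a run still ended in 3 or more T, which argues against left-over adaptor bases as the main cause. Addition of T without a template predicts runs at several positions, and over the 20 stems 51.3% of the reads with a run had it at the stem's end, below the 95% set beforehand. That value came from 5 stems that start like another of them, and over the other 15 the share was 99.0%, so whether the T bases are templated cannot be told apart here without a genome. A candidate explanation is transcripts of RNA polymerase III, which end in a run of U, and this was not tested.

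Reads with a conserved site of bacterial 16S rRNA were above the limit that a count of 0 allows in both libraries, with 1120 reads at stage X and 145 at stage HH10. Relative to library reads they were 7.17-fold higher at stage X (interval 6.03 to 8.59), so part of the 5′ groups with few or no stage HH10 reads may be bacterial. Of the 2315 groups of 24 to 30 nt that were lower at stage HH10, 0 held such a site. The sites are a small part of a bacterial transcriptome, so the size of that part cannot be told apart from chicken RNA without genomes of both.

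Reads shorter than the gel window, which the comparisons leave out, made up 24.7% of the stage X reads and 34.9% of the stage HH10 reads.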

How the results depend on the processing

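The denominator of all reads, the thinned library, the removal of the 1000 most abundant groups, the seeds above the 95th percentile and the textbook continuation were chosen after the data were seen. The read classes, genomic windows, mismatches and single genomic places of the plan were not run because no genome was used. The causes of the changes given here were not tested.

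The higher 24 to 30 nt share at stage X and the higher 20 to 23 nt share at stage HH10 kept their direction under each alternative run. In stage X and stage HH10 order, the 24 to 30 nt share was 41.4% and 27.9% over distinct tags, 51.9% and 31.7% for 23 to 29 nt, 24.8% and 5.86% for 26 to 30 nt, 41.95% and 19.6% for tags read at least 2 times, and 31.6% and 12.99% of all reads. The 20 to 23 nt share was 39.5% and 45.8% over distinct tags, 44.0% and 64.1% for tags read at least 2 times, and 33.0% and 41.3% of all reads. T as first base was 32.6% and 25.5% over distinct tags, 37.8% and 48.0% for 23 to 29 nt, 43.1% and 23.3% for 26 to 30 nt, and 40.6% and 53.9% for tags read at least 2 times, so its direction turned in 2 of these. A as base 10 stayed higher at stage X, with 32.8% and 25.9%, 31.4% and 17.9%, 31.9% and 16.5%, and 33.5% and 15.4% under the same alternatives. Tags read at least 2 times numbered 609485 and 337948.

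The share of 10 nt overlaps stayed higher at stage X throughout. It was 3.04% and 0.954% for 23 to 29 nt, 2.52% and 0.392% for 26 to 30 nt, 3.73% and 0.581% for tags read at least 2 times, and 3.24% in the thinned stage X library. Removal of the 1000 most abundant groups gave 2.73% and 0.862%. The neighbouring overlaps moved with it, and against their mean the 10 nt share was not consistently higher at stage X, with 1.79 and 1.66 times for 23 to 29 nt, 2.08 and 2.43 for 26 to 30 nt, 1.84 and 1.56 for tags read at least 2 times, and 1.67 and 1.79 without the 1000 groups.

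The seed calls depended on the scaling. Against 9 higher and 20 lower, the reads of the library gave 29 and 9, TMM 12 and 17, DESeq2 size factors 15 and 16, the textbook continuation 17 and 9, and the seeds above the 95th percentile 8 and 10. At least 100 reads in 1 library gave 9 and 15, an offset of 5 reads 8 and 20, and no minimum 9 and 20. Scaled to library reads the seed of miR-99 and miR-100 turned to 0.68, miR-196 to 0.49, miR-96 to 0.29 and miR-7 to 0.41, and 12 seeds not called when scaled to seed reads also changed sign, 9 of them to a call of higher. With textbook reads miR-196 turned to 1.32, miR-9 to 0.0856, miR-153 to 0.53, miR-133 to 0.47, miR-96 to 1.45 and miR-217 to 2.90. Of the seeds not called over all seed reads miR-499 turned to 2.29, miR-144 to 1.05 and miR-219 to 3.33, while 27 seeds stayed within their interval. The sign turned for 3 seeds with TMM and 6 with DESeq2 size factors, none of them called. List medians scaled to library reads were 1.04 for miR-17-92, 2.21 neural, 0.36 muscle and heart, 0.91 vessel and blood, 2.74 epithelial, 2.74 sensory, -1.66 mesenchyme, -0.96 endoderm organs and 1.97 widely expressed. With textbook reads they were -0.69 for miR-17-92, 1.06 neural, 0.47 muscle and heart, -0.33 vessel and blood, 1.08 epithelial, 1.45 sensory, -2.29 endoderm organs and 0.23 widely expressed. Depth limits seeds with few reads, such as miR-205 and miR-194, whose intervals span more than 1 on the log2 scale.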

Other observations

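Among the 20 leading stems that end in a run of T, 18 were higher relative to library reads at stage HH10, with a median of 3.40-fold and a range from 0.560-fold to 15.5-fold. Reads of these stems with 3 or more T made up 6.36% of all reads at stage X (interval 6.35 to 6.38) and 26.2% at stage HH10 (26.22 to 26.27). Runs of 3 A, C or G at the read end went the other way, with 2.84%, 2.02% and 1.76% of the 12 to 30 nt reads at stage X and 1.11%, 0.814% and 0.963% at stage HH10. Runs of T were more frequent below the gel window, with 24.02% of the 12 to 17 nt reads at stage X and 55.6% at stage HH10, against 4.43% and 20.3% of the 18 to 30 nt reads.

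Tags paired at 10 nt were most often 26 nt long at stage X, with 20.2% of them, and 24 nt long at stage HH10, with 22.95%. Of the 18704 tags paired at stage X, 2113 were also read at stage HH10, and of the 819 paired at stage HH10, 492 were also read at stage X.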
